A study of Mus musculus with 10 samples.

How the data were processed

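The data are RNA-seq counts from the left ventricle of mice, with 5 libraries from animals on a standard diet (Control) and 5 from animals on a high-fat diet with L-NAME for 6 weeks (HFpEF). Per the labels' protocols, tissue was flash frozen, RNA was extracted with a column kit, ribosomal RNA was depleted and total RNA libraries were built with a Swift Biosciences kit. Whether the libraries keep strand is not given in the sources used here. Bowtie2 2.1.0, RSEM 1.2.15 and build mm10 are named in the submitters' processing notes, without their role. RSEM estimates counts by dividing reads that match several transcripts, and the deposited values, in the unit expected counts, are read as such per gene. They are whole numbers, not normalized, and rounding by the authors is not stated. Of the genes tested, 44 carry values equal to another gene's in every library. The annotation release used by the authors is not given in the sources used here. The deposited table holds 55385 genes and 92 ERCC spike-in sequences, which had 0 counts in every library and were left out.

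Library totals lay between 31286355 and 46108710 counts, and 35413 genes had at least 1 count. Each library was taken as 1 replicate of its group as labelled; all pairs of libraries within a group differed by more than sampling noise in a chi-square comparison of counts. The values were used as deposited, and rounding to whole numbers changed none of them. Symbols and identifiers are those of the table. Coordinates, biotypes, transcript lengths and GC content came from GENCODE M21 (build mm10) by identifier, which matched 55144 of the 55385 genes.

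Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 18491. The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, robust quasi-likelihood fits, group as the sole term and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.0965. Standard errors were taken from the fold change and its F statistic, and intervals are 95%. CPM use the TMM-scaled library sizes. Single library measures were compared with exact permutation tests over all splits, two-sided. On simulated data (5 simulations drawn from the means, dispersions and library sizes of these libraries, with 200 changed genes each and 18168 to 18217 genes tested), the test recovered 14.2% of genes changed 1.2-fold, 61.8% of those changed 1.5-fold and 83.6% of those changed 2-fold, with 5.95% of calls false. The list test called 5 of 5 lists of 30 genes shifted 1.15-fold and 0 of 5 unchanged lists. Simulated genes were drawn independently, while correlations estimated in the data ran from -0.00453 (endocardial and lymphatic markers) to 0.745 (heat shock response). How often the list test falsely calls lists of correlated genes is therefore not shown. Changes near 1.2-fold were thus mostly missed in these simulations. The 5 simulations gave 555 calls in all and the data 985, so the p cutoff was stricter in the simulations. The share recovered in the data may be higher.

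Before the data were examined, 39 gene lists were written for pathways and cell types of the heart; 38 had at least 3 tested members, and the skeletal muscle marker list, with 1, was not tested. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry. Its directional test asks whether a list moves one way, and its mixed test asks whether members change in either direction. With an estimated correlation 1 list stayed called, that of fatty acid oxidation; fry called 11 lists, and its mixed test 27. Fry alone called lipogenesis and cholesterol synthesis and the endocardial and lymphatic markers. The lists that camera called and fry did not were oxidative phosphorylation, mitochondrial transcripts, interferon-stimulated genes, endoplasmic reticulum stress, cell cycle and macrophage markers. Counts of members are given at the adjustment over all genes tested and adjusted over the list alone.

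Genes to name were set by a rule written before the data were examined. It took the FoxO factors, the 10 largest rises and 10 largest falls among calls with a mean log2 CPM of at least 1 (leaving out unnamed gene models), and per list the members with the smallest p, up to a limit. After values had been seen, this last part was narrowed to called members, or the single member with the smallest p where none was called, plus the most expressed member of each marker list. The rule gave 122 genes, of which 102 were called. Of these, 63 stayed called in all 10 fits that left out 1 library. Exons of 19 of the 122 named genes overlap another annotated gene over at least 10% of their length, 15 of them on the opposite strand; without known strand such reads cannot be told apart. Some genes are not reported here one by one, though counts of lists and calls include them.

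Alternatives fixed before the data were examined were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom with quality weights. They further were no filter, a stricter filter (1 CPM in 5 libraries), fits without robust estimation, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a test against a fold change of 1.2, leaving out mitochondrial transcripts, and leaving out each library in turn. Lists were retested in these fits with cameraPR. Added after seeing the data were thinning of all libraries to equal depth, leaving out Control 4 and Control 5, which are the deepest, and an adjustment for transcript length and GC content.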

Results

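RNA was sequenced from the left ventricle of C56Bl6 mice (strain name as in the labels) in 2 groups of 5 libraries. The Control group received a standard diet. The HFpEF group received a high-fat diet with L-NAME, an inhibitor of nitric oxide synthase, for 6 weeks, a regimen that models heart failure with preserved ejection fraction (HFpEF). Total counts per library ran from 31555001 to 46108710 in Control and from 31286355 to 33604554 in HFpEF, with means of 37259108 ± 6470276 and 32596424 ± 1016184 (SD, n = 5; exact permutation test, two-sided p = 0.222). Transcripts of the mitochondrial genome took 35.7% ± 1.70 of the counts in Control and 37.6% ± 0.897 in HFpEF (SD, n = 5; exact permutation test, two-sided p = 0.0635). This share counts genes whose symbols start with mt- and leaves out the gene models Gm28437 and Gm28661. They held 3.85% and 3.72% of all counts, and whether they took reads of mitochondrial transcripts was not tested. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these libraries. Values per gene are CPM, counts scaled to library size with TMM factors, and log2 fold changes are HFpEF against Control with their standard errors (SE). Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 18491 genes tested, and a gene was called higher or lower at an adjusted p below 0.05.

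The comparison asks which ventricular transcripts differed between the groups after 6 weeks of the regimen. A difference in substrain or source of the animals between the groups was not tested and stays open beside the regimen. Of 39 genes of fatty acid oxidation and other targets of the nuclear receptor PPAR alpha, 30 rose. Among them Decr1 rose by 0.79 ± 0.06 and Acot2 by 1.05 ± 0.08 on the log2 scale (SE, 5 libraries a group). Of 23 interferon-stimulated genes 5 fell, as did the clock output genes Ciart, Dbp and Nr1d1 and the natriuretic peptide gene Nppa. Foxo1, the forkhead transcription factor this series is concerned with, showed no detectable difference. In all, 599 genes were higher and 386 lower, 985 calls or 5.33% of the genes tested, and the changes were small, with a median absolute log2 fold change of 0.38 among the calls. A change of at least 1.5-fold was seen for 123 of the higher and 129 of the lower genes. The first principal component held 22.2% of the variance and separated the groups, with all Control libraries at -7.63 or below and all HFpEF libraries at 13.9 or above. The number of calls fell to 554 without HFpEF 3, to 630 without Control 1 and to 633 without HFpEF 4.

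Foxo1 (ENSMUSG00000044167.6; protein-coding, mm10 chromosome 3, 52268336 to 52353221, plus strand) stood at 30.7 ± 1.02 CPM in Control and 30.4 ± 1.29 CPM in HFpEF (SD, n = 5). Its log2 fold change was -0.02 ± 0.05 (SE), with a 95% interval from -0.11 to 0.08 and an adjusted p of 0.893. The sign of this near-zero value turned without Control 2 (0.01) and without HFpEF 2 (0.00). Of the other FoxO factors, Foxo4 rose from 19.9 ± 1.70 to 23.9 ± 1.18 CPM (log2 fold change 0.27 ± 0.06, adjusted p = 0.0210). Leaving out Control 1, HFpEF 3 or HFpEF 4 ended the call of Foxo4, with adjusted p values up to 0.0600. Foxo3 (0.08 ± 0.08, adjusted p = 0.591) and Foxo6 (-0.39 ± 0.19, adjusted p = 0.266) were not called. The FoxO factors thus counted 1 higher, 0 lower and 3 not called, and 1 higher adjusted over the list alone.

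**Figure D1:**
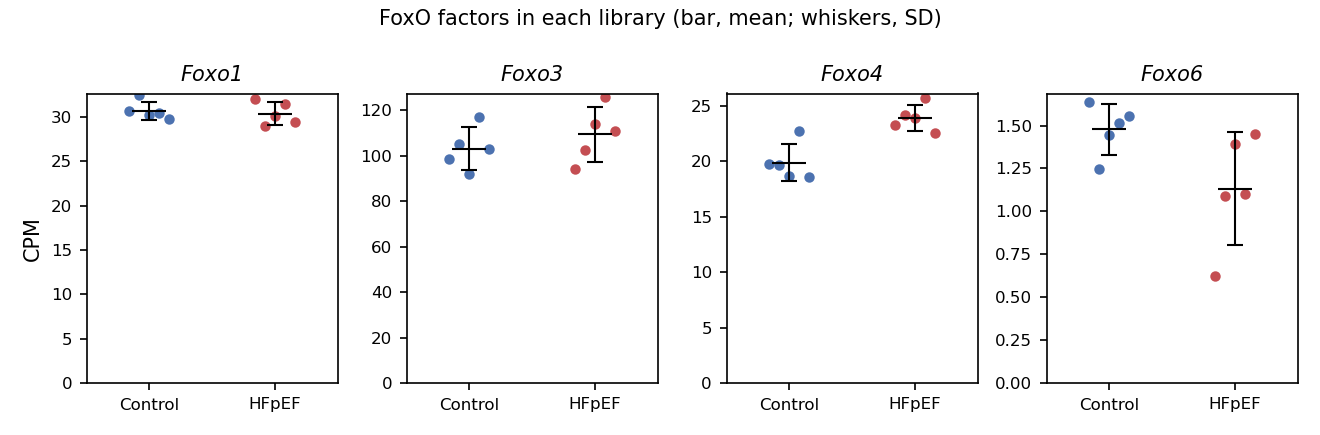
Expression of Foxo1, Foxo3, Foxo4 and Foxo6 in CPM (vertical axis, from 0) in the 5 Control and 5 HFpEF libraries; each point is a library, the bar the group mean and the whiskers the SD. Foxo1 lies at 30.7 CPM in Control and 30.4 CPM in HFpEF.

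Target genes of FoxO factors counted 6 higher, 0 lower and 22 not called among the 28 tested, and 8 higher and 0 lower adjusted over the list alone. Cat, which encodes catalase, rose by 0.35 ± 0.05 on the log2 scale (138 ± 7.21 to 176 ± 8.51 CPM, SD, n = 5; adjusted p = 0.000963). Txnip, a thioredoxin-binding protein, rose by 1.05 ± 0.21 (276 ± 76.8 to 570 ± 111 CPM, adjusted p = 0.0229). Gadd45b rose by 0.98 ± 0.22 (adjusted p = 0.0195) and the transcriptional coactivator Ppargc1a by 0.50 ± 0.11 (adjusted p = 0.0199). The atrogenes Trim63 (0.10 ± 0.08) and Fbxo32 (0.06 ± 0.08) were not called. The list was called up by camera (adjusted p = 1.76e-05; adjusted p = 0.26 with an estimated correlation). It shares 2 tested members with the fatty acid oxidation list and 11 with any other list. The call of Txnip ended without Control 3 (adjusted p = 0.0598), that of Gadd45b without HFpEF 4 (0.0517), and that of Ppargc1a without Control 3 or HFpEF 3 (up to 0.0588). The remaining higher members were Sesn3 (0.21 ± 0.06, adjusted p = 0.0437) and Irs2 (0.42 ± 0.11, adjusted p = 0.0479). Of the 10 fits without 1 library, Sesn3 was called in 3 (adjusted p up to 0.113) and Irs2 in 2 (up to 0.114). Cat alone of the 6 stayed called in all 10.

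Of 39 tested genes of fatty acid oxidation and PPAR alpha targets, 30 rose, 1 fell and 8 were not called, and 33 rose and 1 fell adjusted over the list alone. Decr1, the 2,4-dienoyl-CoA reductase of mitochondria, rose from 164 ± 13.4 to 284 ± 12.6 CPM (SD, n = 5; log2 fold change 0.79 ± 0.06, adjusted p = 5.09e-06). Hadha, the alpha subunit of the trifunctional protein, rose by 0.63 ± 0.06 on the log2 scale (adjusted p = 5.10e-05). Very-long-chain acyl-CoA dehydrogenase (Acadvl, 0.49 ± 0.05), the acyl-CoA thioesterases Acot1 (1.12 ± 0.13) and Acot2 (1.05 ± 0.08), Ech1 (0.80 ± 0.07) and the lipid droplet protein Plin5 (0.57 ± 0.06) rose with them, with adjusted p values of 0.000349 or below. Lpl, lipoprotein lipase, chosen after its value was seen, was the member that fell (-0.26 ± 0.07, adjusted p = 0.0386). Of the 10 fits without 1 library it was called in that without HFpEF 3 alone (adjusted p up to 0.120). Ppara itself was not among the calls, and Pdk4 missed the threshold (1.17 ± 0.31, adjusted p = 0.0675). The median log2 fold change of the list was 0.48, and it was the list called both by camera (adjusted p = 1.54e-64) and with an estimated correlation (adjusted p = 0.0180). Acot1 and Acot2 are neighbouring paralogs on chromosome 12, and exons of Acadvl overlap the opposite-strand gene Dvl2 over 42.9% of their length, so their values are less certain.

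**Figure D2:**
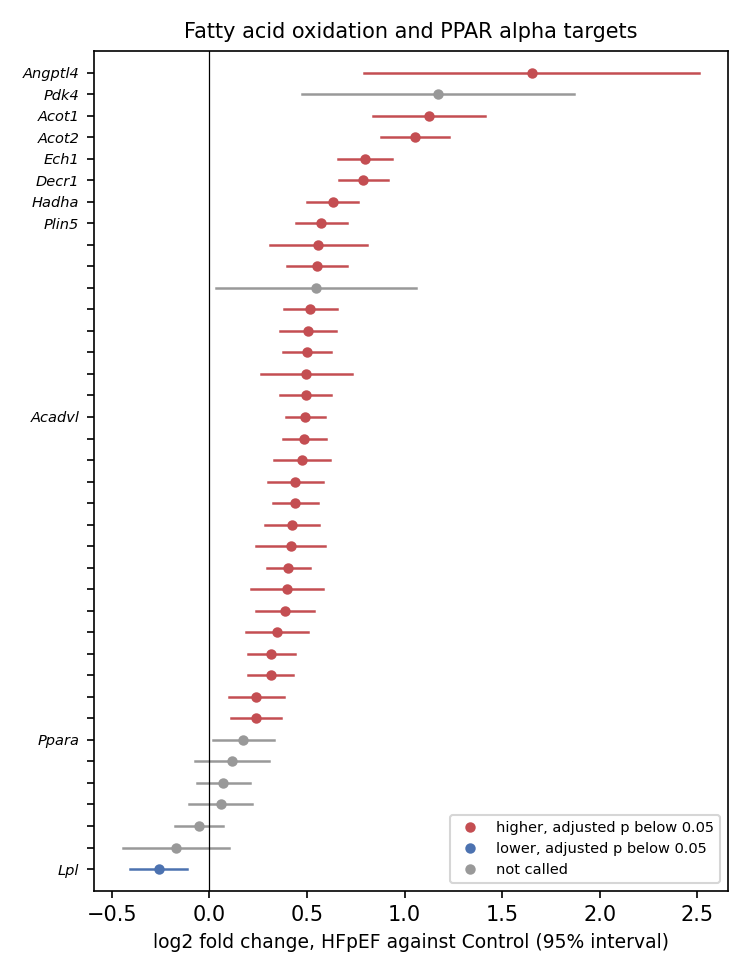
Log2 fold change of HFpEF against Control (horizontal axis) with its 95% interval for 38 genes of fatty acid oxidation and PPAR alpha targets, with genes named in the text marked; red marks 29 higher calls, blue the 1 lower call and grey the 8 genes not called. Decr1 stands at 0.79 and Lpl, the lower call, at -0.26.

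Ketone body genes moved in both directions: 2 rose, 1 fell and 3 were not called of 6, and 2 rose and 2 fell adjusted over the list alone. Acat1, which joins acetyl-CoA units, rose by 0.42 ± 0.06 (adjusted p = 0.000906). Oxct1, which activates ketone bodies for oxidation, fell (-0.36 ± 0.08, adjusted p = 0.0212); its call ended without Control 2, Control 5 or HFpEF 2 (adjusted p up to 0.0610). The list was not called by camera (adjusted p = 0.0755).

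Of 27 genes of glucose uptake and glycolysis, 3 rose, 2 fell and 22 were not called, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.893). The liver-type phosphofructokinase Pfkl rose (0.43 ± 0.05, adjusted p = 0.000398) and so did Pdk1, a kinase that inhibits pyruvate dehydrogenase (0.39 ± 0.07, adjusted p = 0.00366). Hk1 fell (-0.39 ± 0.05, adjusted p = 0.000406) and Eno3 fell (-0.27 ± 0.06, adjusted p = 0.0115). Of 27 genes of lipogenesis and cholesterol synthesis, 1 rose, 3 fell and 23 were not called, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0717; called down by fry, adjusted p = 0.0299). Srebf1 fell by 0.24 on the log2 scale and Acaca, acetyl-CoA carboxylase, fell by 0.28, while Me1 rose by 0.39 (adjusted p = 0.0114, 0.0155 and 0.0119). Insulin signalling counted 4 higher, 1 lower and 16 not called of 21, and 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.269). Pik3r1 (0.39 ± 0.08, adjusted p = 0.0105) and Grb10 (0.29 ± 0.06, adjusted p = 0.010) rose. Akt1 was the member that fell (-0.25 ± 0.06, adjusted p = 0.0276). Its call ended without Control 1, Control 2, HFpEF 3 or HFpEF 5 (up to 0.0804). The other higher members were Irs2, given above, and Pdpk1 (0.16 ± 0.04, adjusted p = 0.0442). Pdpk1 was called in 2 of the 10 fits without 1 library (otherwise up to 0.106). Branched-chain amino acid catabolism had 0 calls among 21 genes by edgeR in either adjustment, 3 genes at an unadjusted p below 0.05 and 1 call each by DESeq2 and voom, and its camera adjusted p was 0.784.

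Nuclear-encoded oxidative phosphorylation genes counted 3 higher, 0 lower and 75 not called of 78 (2 higher adjusted over the list alone), with a median log2 fold change of 0.05. Sdhc rose by 0.26 ± 0.05 and Ndufc2 by 0.27 ± 0.06 (adjusted p = 0.00753 and 0.0124). The list was called up by camera at an adjusted p of 0.0128 (adjusted p = 0.79 with an estimated correlation), and not by cameraPR without Control 3 (0.190) or HFpEF 3 (0.128). Of the 13 transcripts of the mitochondrial genome, 1 rose and 12 were not called, with 5 higher adjusted over the list alone and a median of 0.13 (camera adjusted p = 0.00195; adjusted p = 0.46 with an estimated correlation). The riser was mt-Co3 (0.69 ± 0.16, adjusted p = 0.0357), whose call was kept without Control 1, Control 4 or HFpEF 2 and ended without each of the other 7 libraries (adjusted p up to 0.0890). It stood at 300 ± 69.3 CPM in Control and 485 ± 61.0 CPM in HFpEF (SD), while mt-Co1 held 12.6% of all counts. The gene models Gm28437 and Gm28661 held 3.85% and 3.72%. Whether they took reads of mt-Co3 or other mitochondrial transcripts was not tested, so the value of mt-Co3 is less certain. The list call ended without Control 4 and Control 5 together (adjusted p = 0.161), where the median was 0.06.

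Ion channel genes of the heart, relevant to rhythm, changed in both directions. Of 37 tested, 5 rose, 4 fell and 28 were not called, and 10 rose and 6 fell adjusted over the list alone. Hcn4, the main pacemaker channel, rose from 9.24 ± 0.612 to 12.6 ± 1.21 CPM (SD, n = 5; log2 fold change 0.45 ± 0.08, adjusted p = 0.00279). Kcnj3 (0.30 ± 0.05) and Kcnj5 (0.30 ± 0.05), the subunits of the acetylcholine-activated potassium channel, rose with adjusted p values of 0.00401 and 0.00415, and the calcium channel subunit Cacna2d1 rose by 0.24 ± 0.05 (adjusted p = 0.00911). The cation channel Trpm4 fell (-0.29 ± 0.06, adjusted p = 0.010), and Gja1, which encodes connexin 43, fell (-0.26 ± 0.07, adjusted p = 0.0287). The call of Gja1 was kept without Control 3, Control 4, HFpEF 1 or HFpEF 2 and ended without each of the other 6 libraries (adjusted p up to 0.0877). The remaining calls, chosen after their values were seen, were Kcnd3 (0.26 ± 0.07), Kcnip2 (-0.33 ± 0.08) and Hcn2 (-0.66 ± 0.16), with adjusted p values of 0.0301, 0.0361 and 0.0413. The call of Kcnd3 ended without Control 1, Control 4, Control 5, HFpEF 3 or HFpEF 5 (up to 0.0887). That of Kcnip2 ended without each library but Control 3 and HFpEF 3 (up to 0.0872), and that of Hcn2 without each but Control 3, HFpEF 1 and HFpEF 2 (up to 0.0972). The list did not move one way (camera adjusted p = 0.494, fry adjusted p = 0.269). Fry's test for change in either direction gave an adjusted p of 2.13e-07. That mixed test called 27 of the 38 lists, glycolysis among them with a smaller value (fry mixed adjusted p = 1.02e-09). It therefore does not set the channel genes apart from other lists. A lincRNA on the opposite strand overlaps 31.1% of the exonic bases of Kcnj3.

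**Figure D3:**
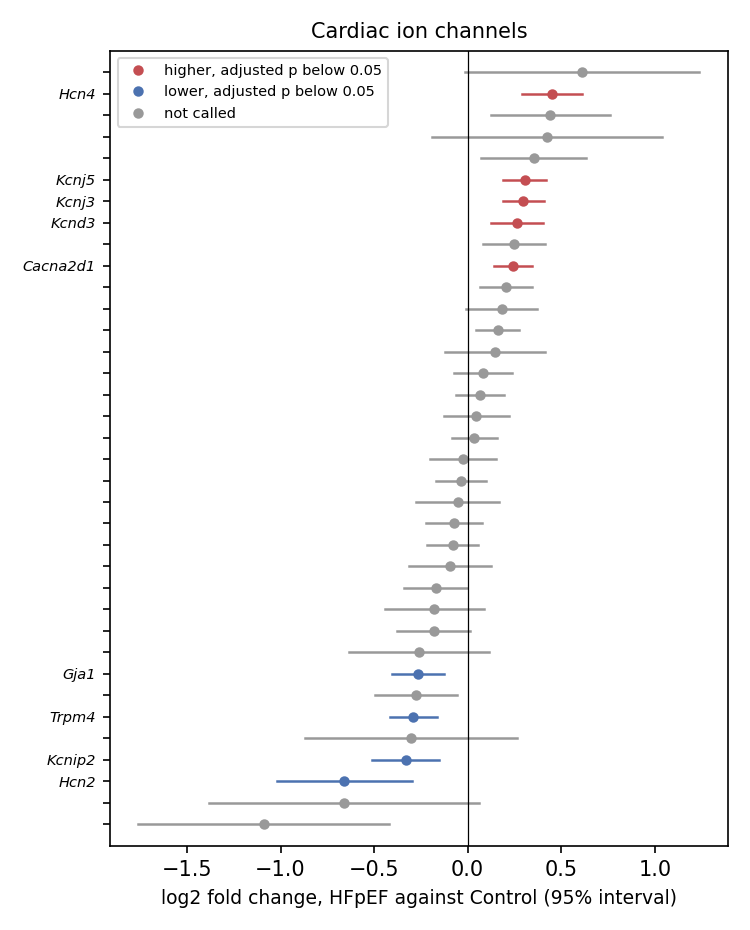
Log2 fold change of HFpEF against Control (horizontal axis) with its 95% interval for 36 cardiac ion channel genes, with genes named in the text marked; red marks the 5 higher calls, blue the 4 lower calls and grey 27 genes not called. Hcn4 at 0.45 is the highest of the calls and Hcn2 at -0.66 the lowest.

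Calcium handling genes counted 2 higher, 0 lower and 31 not called of 33, and 7 higher and 2 lower adjusted over the list alone. Asph, whose locus also encodes junctin, rose from 121 ± 2.61 to 153 ± 5.31 CPM (0.33 ± 0.04, adjusted p = 0.000406). The calmodulin gene Calm3 rose by 0.21 ± 0.05 (adjusted p = 0.0200; not called without HFpEF 2 or HFpEF 4, adjusted p up to 0.0578). The ryanodine receptor Ryr2 (0.12 ± 0.05), the calcium pump Atp2a2 (0.02 ± 0.06) and phospholamban (Pln, 0.04 ± 0.07) were not called. The list was called up by camera with a median of 0.06 (adjusted p = 0.00983; adjusted p = 0.28 with an estimated correlation). Of 16 genes of haemodynamic stress and the fetal programme, 2 rose, 2 fell and 12 were not called, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.893). Nppa (chromosome 4, 148000722 to 148002079, plus strand) fell from 49.3 ± 8.35 to 21.6 ± 6.69 CPM (log2 fold change -1.19 ± 0.22, adjusted p = 0.0187). Nppb (-0.38 ± 0.25, adjusted p = 0.434) and Myh7 (-0.05 ± 0.11, adjusted p = 0.844) were not called. Mt2, given below, was the other member that fell. The members that rose were Fhl1 (0.28 ± 0.06, adjusted p = 0.0182) and Xirp2 (0.33 ± 0.09, adjusted p = 0.0487). The call of Fhl1 ended without Control 1 or HFpEF 3 (up to 0.0566), and that of Xirp2 lasted only without HFpEF 1 (otherwise up to 0.112). An antisense gene covers 61.5% of the exonic bases of Nppa, and its call ended without Control 4 and Control 5 together (adjusted p = 0.0872; 1.50e-05 to 0.103 over all alternatives).

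Among 31 genes of nitric oxide, natriuretic peptide and vasoactive signalling, 3 rose, 1 fell and 27 were not called, and 6 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.494). The alpha-1B adrenergic receptor gene Adra1b rose by 0.72 ± 0.10 (adjusted p = 0.000568) and the endothelin receptor gene Ednra by 0.47 ± 0.07 (adjusted p = 0.00105). The synthase genes Nos3 (-0.13 ± 0.08, adjusted p = 0.365) and Nos2 (-0.23 ± 0.08, adjusted p = 0.0966) were not called.

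Extracellular matrix and fibrosis genes counted 2 higher, 1 lower and 44 not called of 47, with the same counts adjusted over the list alone (camera adjusted p = 0.0755). Thbs1, thrombospondin 1, rose from 5.82 ± 1.01 to 9.64 ± 1.03 CPM (0.72 ± 0.11, adjusted p = 0.00163). The fibrillar collagens Col1a1 (-0.06 ± 0.12), Col1a2 (-0.00 ± 0.09) and Col3a1 (-0.07 ± 0.15) were not called. Fbn1 was the member that fell (-0.38 ± 0.09, adjusted p = 0.0339), kept without Control 1, Control 5 or HFpEF 2 and ended without each of the other 7 libraries (adjusted p up to 0.0877).

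Interferon-stimulated genes counted 0 higher, 5 lower and 18 not called of 23, and 0 higher and 9 lower adjusted over the list alone, with a median log2 fold change of -0.29. Irf9 (-0.43 ± 0.07, adjusted p = 0.00168) and Stat2 (-0.42 ± 0.08, adjusted p = 0.00502), partners in the transcription factor that interferon activates, fell, as did Ifi27l2a (-0.80 ± 0.16, adjusted p = 0.00967). Camera called the list down (adjusted p = 8.97e-07), which ended with an estimated correlation (adjusted p = 0.43) and with fry (0.0959). Inflammatory mediators counted 0 higher, 2 lower and 17 not called of 19, and 5 lower adjusted over the list alone (camera adjusted p = 0.00413; adjusted p = 0.26 with an estimated correlation). With the stricter filter the call of this list ended (adjusted p = 0.0730, median -0.16 against -0.26). The 2 were Cxcl1 (-1.04 ± 0.28, adjusted p = 0.0433) and Icam1 (-0.61 ± 0.16, adjusted p = 0.0494). Their calls lasted only without Control 4 or HFpEF 2 for Cxcl1 (otherwise up to 0.110) and without Control 4 or HFpEF 1 for Icam1 (up to 0.123). Macrophage markers counted 0 higher, 1 lower and 15 not called of 16 (8 lower adjusted over the list alone; median -0.31; camera adjusted p = 0.000393; adjusted p = 0.55 with an estimated correlation and 0.162 with fry; median from -0.39 to -0.18 without 1 library). Folr2 was the member that fell (-0.84 ± 0.19, adjusted p = 0.0187), and not without HFpEF 3 or HFpEF 5 (up to 0.0587). Of the neutrophil markers, 3 were tested, 1 (Csf3r, -0.81 ± 0.23) fell and 2 fell adjusted over the list alone (camera adjusted p = 0.0205; adjusted p = 0.26 with an estimated correlation). The call of Csf3r lasted only without Control 1 or HFpEF 3 (otherwise adjusted p up to 0.112), and that of the neutrophil list ended without Control 4 and Control 5 together (0.134, with the list median at -0.53 against -0.81). Lymphocyte markers counted 0 higher, 1 lower (Ighm) and 7 not called of 8, also adjusted over the list alone, and were not called as a list (camera adjusted p = 0.504). The call of Ighm (-0.33 ± 0.08) ended without Control 2, HFpEF 3 or HFpEF 4 (adjusted p up to 0.0590).

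Ciart (chromosome 3, 95878503 to 95882251, minus strand), a repressor of the clock, fell from 13.7 ± 1.16 to 5.75 ± 0.640 CPM (log2 fold change -1.25 ± 0.09, adjusted p = 1.96e-06). Dbp, a clock-controlled transcription factor, fell (-0.57 ± 0.07, adjusted p = 0.000210), and so did Nr1d1, the nuclear receptor REV-ERB alpha (-0.64 ± 0.09, adjusted p = 0.00101). Of the 19 genes of the circadian list, 2 rose, among them Rora (0.18 ± 0.05), 3 fell and 14 were not called, and 4 rose and 6 fell adjusted over the list alone. The list was called down by camera (adjusted p = 0.00695; adjusted p = 0.26 with an estimated correlation), and not by cameraPR, which takes the gene statistics of the edgeR fit (adjusted p = 0.104). The call of Rora lasted without Control 2, Control 4, HFpEF 1 or HFpEF 2 and ended without each of the other 6 libraries (adjusted p up to 0.0952). Exons of Dbp overlap those of Sphk2 on the opposite strand over 18.0% of their length.

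Immediate early genes counted 4 higher, 0 lower and 19 not called of 23 (7 higher adjusted over the list alone), with a median of 0.31 (camera adjusted p = 2.34e-05; adjusted p = 0.26 with an estimated correlation). Btg2 (0.37 ± 0.08, adjusted p = 0.0112) and Ccn1 (0.33 ± 0.07, adjusted p = 0.0163) rose. The unfolded protein response counted 2 higher, 0 lower and 26 not called of 28, with the same counts adjusted over the list alone, and Atf6, a sensor of endoplasmic reticulum stress, rose by 0.35 ± 0.05 (adjusted p = 0.000684). Its camera call (adjusted p = 0.0424; adjusted p = 0.61 with an estimated correlation) was lost by cameraPR without Control 1, Control 3, Control 4, HFpEF 2 or HFpEF 3 (adjusted p up to 0.148). Autophagy and mitophagy counted 3 higher, 1 lower and 26 not called of 30, also adjusted over the list alone (camera adjusted p = 0.0785). Map1lc3a (0.34 ± 0.05), Ulk2 (0.26 ± 0.04) and Pink1 (0.29 ± 0.05) rose, with adjusted p values of 0.00128, 0.00350 and 0.00593. Ctsl was the member that fell (-0.30 ± 0.05, adjusted p = 0.00390). An antisense gene overlaps 26.8% of the exonic bases of Ctsl, so its value is less certain. Antioxidant defence counted 1 higher, 2 lower and 24 not called of 27, also adjusted over the list alone (camera adjusted p = 0.893); Gclm fell by 0.30 on the log2 scale (adjusted p = 0.0112). The cytosolic heat shock response had 0 calls by edgeR among 16 genes in either adjustment, with 2 at an unadjusted p below 0.05 and 0 calls by DESeq2 or voom (camera adjusted p = 0.893). Cell cycle genes had 0 calls by edgeR among 25 in either adjustment, with 4 at an unadjusted p below 0.05 and 0 calls by DESeq2 or voom. Camera called the list up with a median of 0.29 (adjusted p = 0.0128; adjusted p = 0.61 with an estimated correlation; lost by cameraPR without Control 2, 0.0546, or HFpEF 2, 0.108, and with the stricter filter, 0.0856, where the median was 0.18).

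Cardiomyocyte markers counted 0 higher, 2 lower and 14 not called of 16 (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0595). The troponin genes Tnnt2 (-0.22 ± 0.05, adjusted p = 0.0185) and Tnnc1 (-0.29 ± 0.07, adjusted p = 0.0239) fell. These calls ended without Control 1, HFpEF 2 or HFpEF 4 for Tnnt2 (adjusted p up to 0.0639) and without Control 1, Control 4 or HFpEF 4 for Tnnc1 (up to 0.0709). Endothelial markers counted 0 higher, 2 lower and 12 not called of 14 (4 lower adjusted over the list alone; camera adjusted p = 0.0668), with Pecam1 at 0.00 ± 0.06. Endocardial and lymphatic markers counted 0 higher, 1 lower (Plvap, -0.57 ± 0.16) and 8 not called of 9 (2 lower adjusted over the list alone; camera adjusted p = 0.0785; called down by fry, adjusted p = 0.0299). The call of Plvap lasted only without HFpEF 4 (otherwise adjusted p up to 0.122). By edgeR, 0 of 12 fibroblast, 0 of 12 smooth muscle and pericyte, 0 of 8 mesothelial and 0 of 11 erythroid and platelet markers were called, in either adjustment, and their camera adjusted p values were 0.494, 0.0668, 0.618 and 0.788. At an unadjusted p below 0.05 these lists held 2, 1, 0 and 2 genes, and DESeq2 and voom each called 1 fibroblast marker and 0 of the other markers. Schwann and neuronal markers counted 2 higher, 0 lower and 5 not called of 7 (5 higher adjusted over the list alone; camera adjusted p = 0.000147; adjusted p = 0.26 with an estimated correlation). Dbh, the noradrenaline-synthesizing enzyme, rose from 0.990 ± 0.249 to 2.32 ± 0.480 CPM (1.21 ± 0.19, adjusted p = 0.00168). The Schwann cell cadherin Cdh19 rose by 0.43 ± 0.09 (adjusted p = 0.0135). Of the 15 adipocyte markers, 5 were tested, 2 rose, 0 fell and 3 were not called (3 higher adjusted over the list alone; camera adjusted p = 0.00744; adjusted p = 0.26 with an estimated correlation). With no filter the call of this list ended (adjusted p = 0.103) and its median was 0.01 against 0.20. Cidea (0.64 ± 0.12, adjusted p = 0.00796) and Lipe (0.31 ± 0.07, adjusted p = 0.0153) rose. Atrial markers counted 2 higher, 1 lower (Nppa) and 6 not called of 9, also adjusted over the list alone (camera adjusted p = 0.661). Conduction system markers counted 1 higher (Hcn4), 0 lower and 8 not called of 9 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.893).

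Camera called 15 of the 38 lists tested, 10 up and 5 down. The signs of the list median, mean and camera test differed for the FoxO factors, cardiac ion channels, nitric oxide and vasoactive signalling, glycolysis, heat shock response and branched-chain amino acid lists, none of which was called. The sign of no called list's median turned under RLE or upper quartile scaling; the medians of the nitric oxide, fibroblast, branched-chain amino acid, erythroid and glycolysis lists, all within 0.02 of 0, turned under one of them.

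Among the largest rises was that of the endothelin gene Edn3 (1.24 ± 0.540 to 3.70 ± 0.540 CPM; log2 fold change 1.56 ± 0.23, adjusted p = 0.00184). The nicotinic receptor subunit Chrna2 (1.42 ± 0.22, adjusted p = 0.00263) and the phosphodiesterase Pde11a (1.32 ± 0.21, adjusted p = 0.00331) rose too. Angptl4 (1.65 ± 0.38, adjusted p = 0.0417) and the transferrin receptor Tfrc (1.30 ± 0.27, adjusted p = 0.0313) rose. These calls lasted only without HFpEF 1 or HFpEF 4 for Angptl4 (otherwise up to 0.0856) and without Control 5 or HFpEF 1 for Tfrc (up to 0.0766). The largest falls included those of Scgb1c1 (-1.60 ± 0.24, adjusted p = 0.00191) and the GABA transaminase gene Abat (19.9 ± 2.72 to 7.97 ± 2.75 CPM; -1.33 ± 0.23, adjusted p = 0.0118). The slow skeletal troponin gene Tnnt1 (-1.29 ± 0.20), Cpxm2 (-1.23 ± 0.19) and the threonine-degrading enzyme Gcat (-1.07 ± 0.19) fell, with adjusted p values of 0.00212, 0.00446 and 0.00415. The metallothionein Mt2 (-1.63 ± 0.35, adjusted p = 0.0290) and Gnb3 (-1.20 ± 0.30, adjusted p = 0.0408) fell as well. The call of Mt2 ended without Control 2, HFpEF 1, HFpEF 2, HFpEF 4 or HFpEF 5 (up to 0.0740). That of Gnb3 lasted only without Control 2, Control 5, HFpEF 1 or HFpEF 3 (otherwise up to 0.0904). Ccn5 fell by 1.10 (adjusted p = 0.0154). The U3 small nucleolar RNA genes Rnu3b1, Rnu3b3 and Rnu3b4, each at 1.12 ± 0.15, had identical counts in every library and are near-identical copies. A second gene of the same symbol overlaps 99.5% of the exons of each on the same strand. That of Rnu3b1 stood at -0.37 ± 0.12 and was not called (adjusted p = 0.103), and the related Rnu3a fell (-0.64 ± 0.14, adjusted p = 0.0247), so the direction of change of U3 RNA is uncertain. Opposite-strand genes overlap exons of Mt2 (73.5%), Folr2 (63.1%), Fbn1 (20.1%), Txnip (19.4%), Scgb1c1 (18.7%), Lipe (15.6%), Asph (14.3%), Oxct1 (12.6%) and Icam1 (11.7%), and a duplicate annotation overlaps those of Gcat (47.5%), so their values are less certain.

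**Figure D4:**
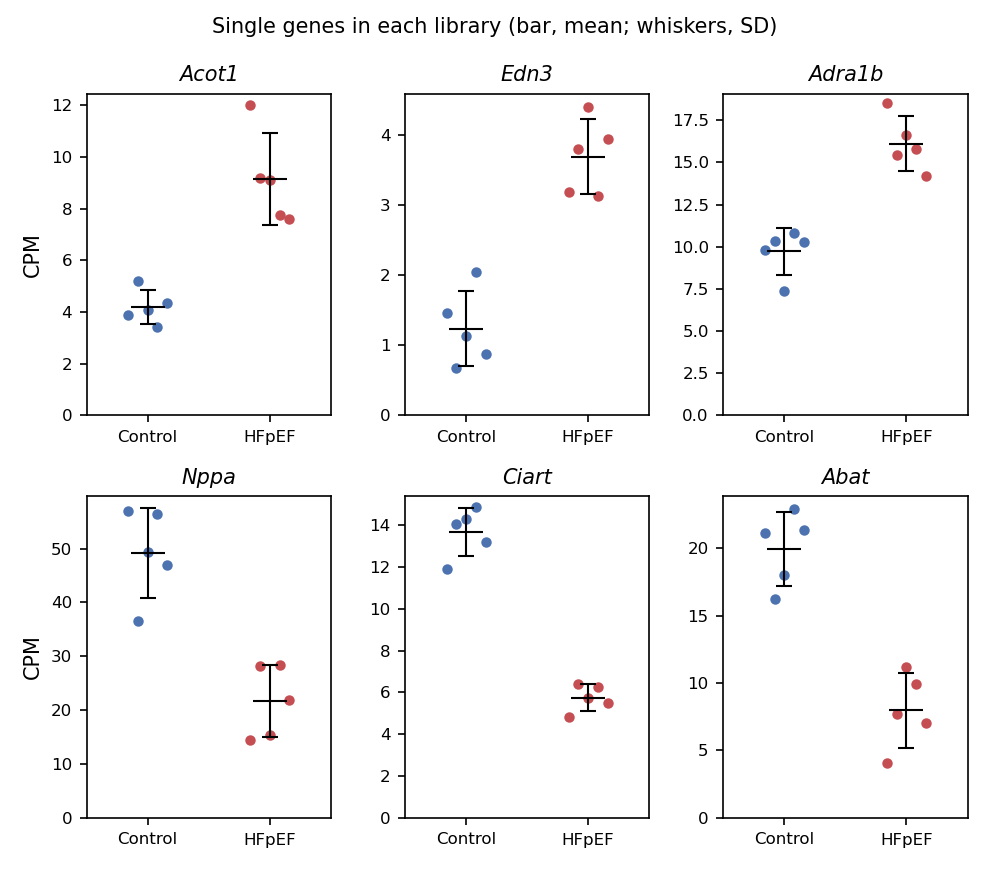
Expression in CPM (vertical axes, from 0) of Acot1, Edn3, Adra1b, Nppa, Ciart and Abat in the 5 Control and 5 HFpEF libraries; each point is a library, the bar the group mean and the whiskers the SD. The mean of Ciart goes from 13.7 to 5.75 CPM and that of Acot1 from 4.20 to 9.13 CPM.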

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

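The tests for clock phase, for atrial tissue and for other splits of the libraries were chosen after the result was seen; the criterion of the atrial test was reworded after its values were seen. The test on leukocyte genes was written before its values were seen, but its demand that a permutation test separate the groups was added afterwards. A library far from the other 4 of its group, by the size of its gap relative to the group's range, was found in 12 of 246 groups of values. Chance gives about 12.3 of 246 groups, or 1 in 20. HFpEF 1 was the outlying library in 5 of them and Control 5 in 4. HFpEF 1 was high for Angptl4 (23.3 CPM) and Txnip (767 CPM) and low for Grb10 (64.5 CPM), Acadvl (275 CPM) and Bckdha (119 CPM). Control 5 was high for Tnnt1 (5.38 CPM), Gpx1 (20.9 CPM) and Tbx3 (26.0 CPM) and low for Hcn4 (8.17 CPM). Control 3 was low for Adra1b (7.35 CPM), HFpEF 3 high for Cacna2d1 (247 CPM) and HFpEF 5 low for Map1lc3a (138 CPM).

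Of 100 splits of the 10 libraries into 5 and 5, drawn from 126, 1 gave as many called genes as the real one with its 985 calls, namely the real one itself, and the highest of the others gave 28. The real split thus ranked first among those drawn, and 1 of 100 is the smallest share that 100 splits can give. Each other split mixes Control and HFpEF libraries on both sides, so a group difference adds to the spread within each side. That can lower their calls, so the gap between 985 and 28 does not measure how unlikely chance is. The rank does not rest on the size of that gap. First place among 100 splits argues against chance as the source of the number of calls, at a share of 1 in 100 and no smaller. It does not tell the regimen from any other difference between the groups.

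Nppa was lower in HFpEF. Atrial tissue in the Control libraries could raise Nppa there, but would bring the other abundant atrial transcripts with it. Sln, Myl4 and Myl7 together stood at 1.03 CPM in Control and 0.967 CPM in HFpEF, against the 27.6 CPM that Nppa lost (SE of the difference 4.79), which argues against atrial tissue. Without the deepest libraries, Control 4 and Control 5, the log2 fold change of Nppa went from -1.19 ± 0.22 to -1.14 ± 0.28 (SE), so the call ended (adjusted p = 0.0872) with a larger error from fewer libraries, while at equal depth Nppa stayed called (-1.20 ± 0.23, adjusted p = 0.0214; 1.50e-05 to 0.103 over all alternatives). An effect of the diet and L-NAME stays open and was not tested separately, nor was that of the antisense gene over its exons.

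Clock output genes Ciart, Dbp and Nr1d1 were lower in HFpEF. A candidate explanation is tissue collection at a different time of day, which would raise genes of the opposite phase: Arntl, Npas2, Clock, Cry1 and Nfil3 had a median log2 fold change of 0.29 (SD 0.18 over the 5 genes), 4 above 0 and none of the 5 called (lowest adjusted p = 0.0907). Further genes near the phase of Dbp, namely Per1, Per2, Per3, Nr1d2, Tef, Hlf and Bhlhe41, lay below 0 in 7 of 7 with a median of -0.12, and none was called. Of these, Hlf (-0.01 ± 0.07) and Per2 (-0.02 ± 0.08) lay within their SE of 0, and Bhlhe41 was lowest (-0.24 ± 0.09). The collection time is not given in the sources used here, so an effect of high-fat feeding on the clock itself stays open beside it and was not tested.

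The interferon, inflammatory, macrophage and neutrophil lists were called lower in HFpEF with a fixed correlation between genes, and none of the 4 with an estimated one (camera adjusted p = 0.43, 0.26, 0.55 and 0.26). A lower share of leukocytes may account for the lower macrophage and neutrophil lists. Whether it accounts for the interferon and inflammatory lists, with medians of -0.29 and -0.26, was not tested separately. The medians of the macrophage, neutrophil and lymphocyte lists were -0.31, -0.81 and -0.07, which met the condition as first written. The pan-leukocyte genes Ptprc, Laptm5, Coro1a, Cd53 and Tyrobp had a median log2 fold change of -0.16, below 0 in 5 of 5. None of the 5 was called. The difference in their mean log2 CPM was within the spread between libraries (exact permutation test, two-sided p = 0.317), so a smaller leukocyte share stays open. Counts from whole ventricle tissue cannot tell it from lower expression per cell, whatever the spread. An effect of the regimen on immune cells stays open.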

How the results depend on the processing

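Thinning, leaving out Control 4 and Control 5, and the length and GC adjustment were chosen after seeing the data; the other alternatives were fixed before. The 985 calls (599 higher, 386 lower) became 1448 (926 and 522) with DESeq2, 1307 (781 and 526) with voom, 1575 (926 and 649) with 1 surrogate variable and 120 (77 and 43) when tested against a fold change of 1.2, which also left 14 fatty acid oxidation genes higher and 9 lists called; with an estimated correlation 1 list was called. The surrogate variable removes spread within groups, and the fold test asks for larger changes. The cause of the DESeq2 and voom counts was not tested. RLE scaling gave 999 calls (624 higher, 375 lower) and upper quartile scaling 976 (526 and 450). Higher genes made up 53.9% of the calls with upper quartile scaling, against 60.8% in the main fit. The excess of higher over lower calls thus depends in part on the scaling. Without 1 library the calls ranged from 554 to 1101 (352 to 684 higher, 202 to 417 lower), fatty acid oxidation genes higher from 26 to 30 and lists called from 13 to 19, with fewer samples in each fit. Foxo1 ranged from -0.03 to 0.01 (-0.0346 to 0.0125) and turned positive without Control 2 and without HFpEF 2 (0.00141); Fabp4, not called, ranged from -0.00746 to 0.0980 and turned without HFpEF 1. No called gene changed sign in an alternative that tested it, leave-one-out fits included; some of the 985 were not tested in some alternatives. Equal depth gave 949 calls and kept 89.2% of the 985, the length and GC adjustment gave 1079 and kept 94.1%, and leaving out Control 4 and Control 5 gave 773 and kept 60.9%; that last fit also ended the list calls of neutrophil markers and mitochondrial transcripts. Over the alternatives the list medians kept their sign and ranged from -0.43 to -0.22 for interferon-stimulated genes, -0.42 to -0.16 for inflammatory mediators, -0.39 to -0.18 for macrophage markers, -1.02 to -0.53 for neutrophil markers, -0.09 to -0.03 for the circadian list, 0.18 to 0.40 for cell cycle, 0.06 to 0.18 for mitochondrial transcripts, 0.03 to 0.08 for oxidative phosphorylation, 0.02 to 0.09 for endoplasmic reticulum stress and 0.01 to 0.26 for adipocyte markers. The call of the circadian list was lost in all alternatives tested with cameraPR but DESeq2 and no filter, and was lost with cameraPR on the same fit too. Over 2926 values of the 122 named genes under alternatives, 2520 kept their side of the threshold and direction, 387 lost the call, 16 gained it and 3 turned. With the replicate number as a block, 744 genes were called (444 higher, 300 lower); same-numbered libraries did not deviate together (correlations of 0.06, -0.11, -0.07, 0.06 and -0.11), so the numbers do not pair the libraries.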

Other observations

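The genes in this part were chosen after their values were seen. Among genes outside the fixed lists, Ephx2, soluble epoxide hydrolase, rose by 0.66 ± 0.05 on the log2 scale (adjusted p = 9.35e-06), Pex11a, a peroxisome proliferation factor, by 0.66 ± 0.08 (adjusted p = 0.000210) and the carboxylesterase Ces1d by 0.59 ± 0.06 (adjusted p = 0.000110). The peroxisomal protein Hsdl2 rose by 0.62 ± 0.07 (adjusted p = 0.000141), the lipid droplet protein Plin4 by 0.56 ± 0.08 (adjusted p = 0.000618) and monoacylglycerol lipase, Mgll, by 0.37 ± 0.05 (adjusted p = 0.000903). Pcx, pyruvate carboxylase, fell by 0.45 (adjusted p = 0.000993) and Pfkfb3, which makes the activator of phosphofructokinase, fell by 0.66 (adjusted p = 0.00246). Bdh1, the mitochondrial enzyme that interconverts ketone bodies, stood at 46.5 ± 7.26 CPM in Control and 19.8 ± 8.72 CPM in HFpEF (SD, n = 5), yet missed the threshold (log2 fold change -1.24 ± 0.34, adjusted p = 0.0825).

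The guanylate-binding protein genes Gbp9 (-0.45 ± 0.08, adjusted p = 0.00637) and Gbp5 (-0.45 ± 0.10, adjusted p = 0.0182) fell. So did Parp14 (-0.34 ± 0.07, adjusted p = 0.00913), the RNA editing enzyme Adar (-0.36 ± 0.06, adjusted p = 0.00255) and the immune checkpoint ligand Cd274 (-0.62 ± 0.14, adjusted p = 0.0202). The call of Gbp5 ended without HFpEF 3 (adjusted p = 0.0551) and that of Cd274 without Control 3, HFpEF 3 or HFpEF 5 (up to 0.0575). The growth factors Nrg1, neuregulin 1, (-0.93 ± 0.19, adjusted p = 0.0183) and Angpt1, angiopoietin 1, (-0.55 ± 0.10, adjusted p = 0.010) fell; the call of Nrg1 ended without HFpEF 5 (0.0512).

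The gene models Gm10778 and Gm4767 were near on or off between the groups. Gm10778 (chromosome 10, 81649059 to 81667361) stood at 3.70 ± 0.270 CPM in Control and 0.115 ± 0.0385 CPM in HFpEF, and Gm4767 (chromosome 10, 81812186 to 81826490) at 0.111 ± 0.122 and 3.44 ± 0.429 CPM (SD, n = 5). Of the 50-base windows of their transcripts, 96.8% of those of Gm10778 also occur in Gm4767. The sum of both genes was 3.81 ± 0.252 CPM in Control and 3.55 ± 0.428 CPM in HFpEF (exact permutation test, two-sided p = 0.294). The values of these copies are uncertain, since reads of one can be counted for the other. Gm45507, an antisense gene on chromosome 7 (138890964 to 138894675), went from 0.0872 ± 0.179 to 2.37 ± 0.677 CPM. The labels give 1 strain name for all 10 libraries and no substrain or source. Nnt, of which C57BL/6J lacks several exons that C57BL/6N has, held 8730 to 12909 counts in each library and did not differ between the groups past the threshold (0.16 ± 0.06, adjusted p = 0.159). Counts per gene do not show which exons were read. A difference in substrain or source of the animals between the groups was not tested further and stays open, for these gene models and for every other difference between the groups.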
